A study of Lactococcus cremoris subsp. cremoris NZ9000 with 2 samples.

How the data were processed

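RNA of 2 BcaP-overproducing cultures and 2 vector control cultures of Lactococcus lactis NZ9000 was measured on 2 dual-channel DNA arrays, 1 culture of each kind per array. Per the labels' protocols, RNA was reverse transcribed with amino-allyl nucleotides and the complementary DNA was coupled to Cy3 or Cy5. On array 1 overproduction was in Cy5 and control in Cy3, and on array 2 the dyes were swapped. The labels call the cultures independently grown, and they do not say whether the control cultures also received nisin. The protocol text counts more replicate cultures than there are arrays, and only those on the 2 arrays were analysed here.

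The deposited scanner files give each spot's intensity in both channels on a linear scale, for 5422 spots in 24 grids. The deposited intensity values hold neither background columns nor spot marks, and exact zeros occur, so they were taken as already background subtracted. The design had set normexp with an offset of 50 for uncorrected signals only, so neither was applied. The counts of calls with and without that offset had been seen when this choice was settled. The scanner, the spot-finding software and the background correction are not given in the sources used here. The deposited value table holds natural log ratios. Set against the scanner values, its columns matched the mean natural log of Cy5 over Cy3 per probe with no centring: 93.7% of probes on array 1 and 96.9% on array 2 lay within 0.01, and the correlations with overproduction over control were 0.998 and -0.998. Column medians were -0.112 and -0.605, and the second column therefore runs as control over overproduction. Of its 2538 probes, the 2431 with a value on both arrays were used as an alternative, turned to overproduction over control and centred.

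Spots at 0 in either channel were left out, and log2 ratios were normalized by loess within each array. Before this step the median log2 ratio was -0.16 on array 1 and 0.87 on array 2. The 2 spots of a probe were then averaged. Spot pairs correlated at 0.651 on array 1 and 0.683 on array 2, with a spot SD of 0.52 and 0.58 on the log2 scale. A ratio on both arrays was available for 2587 probes of 2275 genes. The other 124 probes, with a highest signal of 76.4 units, were not tested. Where a gene had several probes, the brightest stood for it. Of 271 genes with several probes, 108 had probes of opposite sign, and of 155 genes with several probes outside the dimmest 25% of probes, 49 did. Gene names and locus tags are those of the array and can be old: bcaP is named ctrA there, the CesSR pair is named kinD and llrD, and trmA and pheT each name 2 genes. The reference table given was of another strain without these tags and was not used, so no coordinates are printed.

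The mean of the 2 ratios was tested with limma 3.58.1 in R 4.3.3 (intercept model, moderated variances, two-sided, Benjamini-Hochberg adjusted p below 0.05 over all probes), with 1 residual and 4.17 prior degrees of freedom. The 2 arrays allow no exact test below p = 0.5, so every p rests on variances shared between genes. Before the data were examined, 23 gene lists, the tests, the alternatives and the rule for named genes were fixed. The lists were the overproduced gene, CodY-regulated uptake, branched-chain amino acid synthesis, glutamate and glutamine, serine to cysteine synthesis, histidine and aromatic amino acids, arginine, CesSR, chaperones and proteases, protein export, cell wall, fatty acids and phospholipids, ribosomal proteins, aminoacyl-tRNA synthetases, purines, pyrimidines, glycolysis, sugar uptake, ATP synthase, multidrug and nisin, metals, oxidative stress and ribonucleotide reduction, and cold shock and competence. The 22 lists with at least 3 measured members were tested with camera (preset correlation 0.01, 1 probe per gene, adjusted over the lists). The rule named bcaP, the 6 genes with the smallest p on each side where none passed, and up to 4 members per list with the largest mean ratio of the same sign on both arrays. Further list members are named in the text because they passed over their list alone or show the spread of the list, and these were chosen after their values were seen.

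Alternatives for normalization were median centring, print-tip loess and scaling of the arrays. Others left out the dimmest 25% of probes, used the value table, fitted spots with their duplicate correlation (0.754), fitted the channels separately (statmod 1.5.0 for the intraspot correlation of 0.299), or dropped the variance moderation. Set tests were repeated with an estimated correlation, on ranks and with fry. Added after seeing the data were an offset of 50 units with spots at 0 left out or kept, an intensity trend in the variance, subtraction of grid means, lists without bcaP and all probes of a gene.

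The scripts were tested on 10 simulated sets of 2587 probes with the spread found between the real arrays. With an adjusted p, limma found 3.47% of probes changed by 1 on the log2 scale, 54.5% at 2 and 83.8% at 3. At an unadjusted p below 0.05 it found 61.4%, 96.8% and 99.9%, with 5.13% of unchanged probes. Over the 10 sets 81 unchanged probes were called with an adjusted p. Camera found 5 of 5 shifted lists and called 1 of 215 unshifted ones. The simulated probes varied independently of each other, so these counts do not show how often camera errs on correlated genes. The 2 spots of a simulated probe also scattered less than real ones. All simulated probes of a brightness group shared the same spread, which real probes need not do. The shares found may therefore overstate what limma could find on the real arrays, and a gene that did not pass there is not shown to be unchanged.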

Results

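The arrays compared messenger RNA of Lactococcus lactis NZ9000 cells that overproduced BcaP, a permease for branched-chain amino acids, with that of control cells carrying the vector pNZ8048. NZ9000 is a laboratory strain of a dairy lactic acid bacterium (Lactococcus cremoris subsp. cremoris in the labels) whose chromosome carries the nisin sensor genes, so that a gene behind the nisin promoter of a plasmid is switched on by adding this peptide. The overproducing cells carried bcaP on the plasmid pNZbcaP-H6. Cells were grown to an OD600 of 0.5 in GM17 medium, and RNA was compared 1 hour after nisin induction. There were 2 cultures of each kind, grown and harvested independently, and each overproducing culture shared 1 dual-channel DNA array with 1 control culture. The dyes were swapped on array 2. Each array carried 2711 gene probes for 2358 genes, with 2 spots per probe. The median spot signal on array 1 was 63.2 units for overproduction and 76.25 units for control, and on array 2 it was 338.9 and 173.5 units. Between 1.46% and 5.50% of spots per channel had a signal of 0. Every ratio below is overproduction over control, on the log2 scale, as the mean of the 2 arrays unless 1 array is named. A value after ± is the SD between them (n = 2 arrays), and it is not printed for every gene. The number of arrays limits the precision of each ratio.

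The comparison asked which transcripts differed between BcaP-overproducing cells and vector controls. The bcaP transcript itself was 88.4-fold higher in the overproducing cultures (log2 6.47 ± 1.31 SD, n = 2). Cell envelope stress genes of the CesSR system and genes for chaperones and proteases were higher as groups, with llmg_2164 at 13.1-fold and dnaK at 4.93-fold. The uptake list, of peptide and amino acid transporters and peptidases, was lower as a group, as was the purine synthesis list. In them oppF was 5.87-fold lower and purC 6.68-fold lower (4.40-fold and 2.92-fold with 50 units added to each signal). The uptake list was mixed, with a log2 median of -0.64, and of -0.34 outside the dimmest 25% of probes. Outside these dim probes its peptidase genes ran from 0.43 (pepA) to -0.94 (pepO). Its oligopeptide transporter genes ran from -1.71 (oppA) to -2.55 (oppF). The CesSR, chaperone, uptake and purine groups passed the set test with a preset correlation between genes. No single gene passed the test over all probes. With an estimated correlation none of the 4 groups passed (adjusted p = 0.602 for each), and with fry, limma's rotation test, 0 lists passed. Both tests rest on the 1 residual degree of freedom of the 2 arrays, so hardly any list could pass them. They therefore cannot show whether correlated genes made the 4 groups pass. The estimated correlations were -0.018 (CesSR), 0.088 (chaperones), -0.037 (uptake) and -0.011 (purines), against the preset 0.01. They rest on the same 1 residual degree of freedom, so they cannot show that the members varied nearly independently. The CesSR and branched-chain synthesis lists, with 11 members each, had the same estimate of -0.018.

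The gene bcaP (llmg_0118, named ctrA on the array) had a log2 ratio of 7.39 on array 1 and 5.54 on array 2. Among the 2275 genes measured, this was the highest ratio on array 1 and rank 2 on array 2. Its adjusted p in limma was 0.112. It passed in limma when spots were fitted with their duplicate correlation (adjusted p = 0.0251). That fit counts both spots of each array as values, though there were only 2 cultures of each kind. It also passed when the dimmest 25% of probes were left out. In the latter fit the adjusted p was 1.47e-66 with the single spread that limma assigned to all probes, and 0.0338 with the prior degrees of freedom held at 4.17, a test chosen after seeing the data. Over all alternatives its adjusted p ran from 1.47e-66 to 0.681.

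Over all 2587 probes tested, limma called 0 at an adjusted p below 0.05, and the lowest adjusted p was 0.112. Of these probes 31.1% were higher on both arrays, 30.4% lower on both and 38.5% of opposite sign. The counts of list members below are to be read against these shares. At an unadjusted p below 0.05 there were 364 probes, 183 higher and 181 lower, where 129 are expected with no difference. In 4 equal groups of probes, from the dimmest to the brightest, there were 89, 97, 91 and 87. The dimmest group held about as many although its arrays did not agree (r = -0.14). The excess over 129 alone therefore does not show reproducible differences. Besides bcaP, the genes with the smallest p on the higher side were llmg_2163 (3.44 ± 0.16), pacL (3.15 ± 0.13), llmg_2164 (3.71 ± 0.71), dnaK (2.30 ± 0.30) and trmA (llmg_1155, 2.29 ± 0.32). The gene pacL encodes a cation-transporting ATPase. On the lower side they were pbuO (-2.95 ± 0.03), llmg_0974 (-2.99 ± 0.32), ribB (-2.79 ± 0.03), llmg_0245 (-3.07 ± 0.59), oppF (-2.55 ± 0.13) and purH (-2.53 ± 0.22). The gene ribB belongs to riboflavin synthesis and pbuO is named as a purine base permease. None of these 11 genes passed over all probes in limma, with adjusted p between 0.112 and 0.115. The gene llmg_0245 lay in the dimmest 25% of probes with signals of 0.05 to 1.2 units, and its ratio was -0.017 with 50 units added to each signal. Further probes of these genes gave smaller ratios: pbuO had 1 at -1.33, pacL had 1 at 1.13, and purH had 2, at -1.67 and, for a probe among the dimmest 25%, at 0.62. With the dimmest 25% of probes left out, limma called 272 of 1940 probes, 138 higher and 134 lower, under a fit that assigned a single spread to all probes. With the prior degrees of freedom held at 4.17, the count for the same probes was 26, 8 higher and 18 lower. The count was 45 with 50 units added to each signal, an alternative chosen after seeing the data. The ratios of genes with a low signal in 1 or both channels were then smaller, with bcaP at 5.79, llmg_2163 at 2.55, pacL at 2.38 and llmg_0974 at -1.91.

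**Figure D1:**
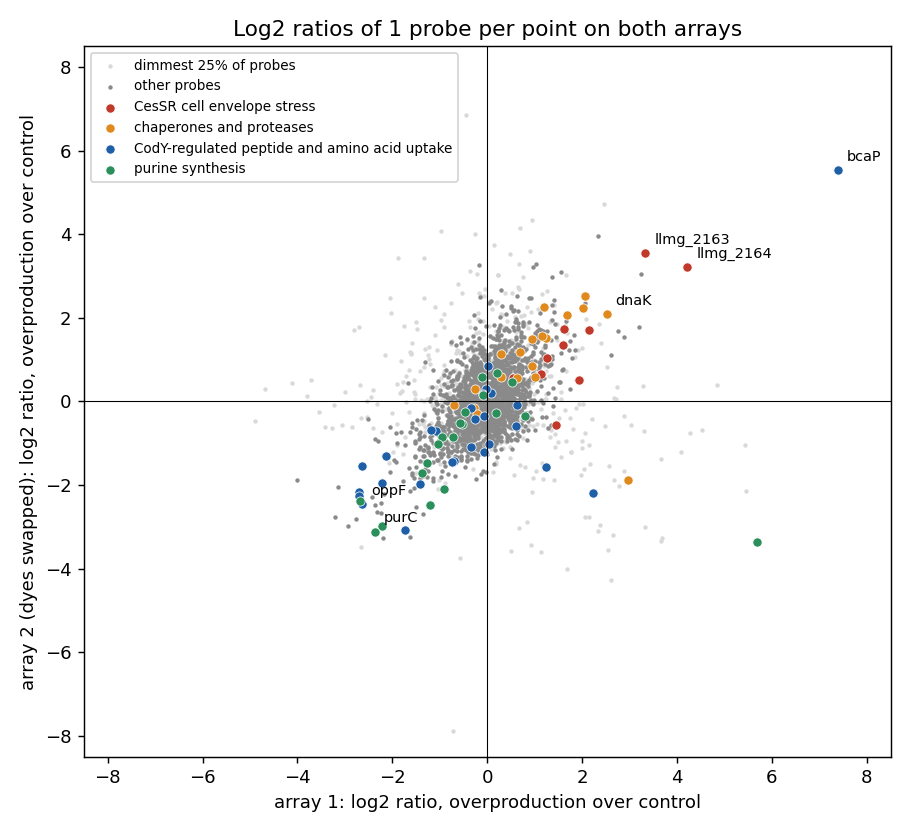
Log2 ratio of overproduction over control on array 1 (horizontal axis) and on array 2 with swapped dyes (vertical axis), 1 point per probe, with members of the 4 gene lists past the set test in colour. Most labelled genes lie near the diagonal, with bcaP at 7.39 and 5.54, while the dimmest 25% of probes, in light grey, scatter into the quadrants of opposite sign.

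Of the CesSR list, the sensor and regulator of cell envelope stress with genes named alongside them, 11 members were measured, and 10 were higher on both arrays and 0 lower on both. The list median was 1.48, a 2.78-fold higher level. The genes llmg_2164 (3.71 ± 0.71) and llmg_2163 (3.44 ± 0.16) led the list. They were followed by trmA (llmg_1155, a regulator of the Spx family also called spxB) at 2.29 ± 0.32 and llmg_0169 at 1.93 ± 0.31 (0.88 with 50 units added to each signal). The regulator gene llrD (llmg_1648) stood at 1.48 ± 0.17 and the sensor gene kinD (llmg_1649) at 1.22 ± 1.00. The list passed camera, limma's set test, with a preset correlation between genes (adjusted p = 1.38e-08), and did not pass with an estimated correlation (adjusted p = 0.602). Over all probes 0 members passed, and adjusted over the list alone 7 passed, all of them higher.

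Of the chaperones and proteases, 19 members were measured, 14 higher and 3 lower on both arrays, with a median of 0.90 (1.87-fold). The highest ratios were those of dnaK, the main Hsp70 chaperone gene, at 2.30 ± 0.30 and trmA (llmg_1155) at 2.29 ± 0.32, followed by the exchange factor gene grpE at 2.12 ± 0.15 and the heat shock repressor gene hrcA at 1.88 ± 0.27. The chaperonin gene groES was at 1.73 ± 0.74, and the Clp genes clpB, clpP and clpE were at 1.38, 1.37 and 1.21. The Clp genes clpC (-0.25) and clpX (-0.21) and the redox chaperone gene hslO (-0.40) were the members below 0 on both arrays. The list passed camera with the preset correlation (adjusted p = 4.35e-06) and did not pass with an estimated correlation (adjusted p = 0.602). Adjusted over the list alone 8 members passed, all higher, against 0 over all probes, and trmA (llmg_1155) is counted in this list and in the CesSR list.

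Of the CodY-regulated uptake list, which holds peptide and amino acid transporters and peptidases named as targets of the repressor CodY, 27 members were measured, 17 lower and 3 higher on both arrays. The median was -0.64 (1.56-fold lower), with -0.33 on array 1 and -1.09 on array 2, and it was -0.34 over the 19 members outside the dimmest 25% of probes. Genes of the oligopeptide transporter were lower throughout: oppF was at -2.55 ± 0.13, oppD at -2.49 ± 0.31, oppB at -2.44 ± 0.38, oppC at -2.08 ± 0.20 and oppA at -1.71 ± 0.58. The di- and tripeptide transporter gene dtpT was at -2.09 ± 0.78 and brnQ, a further branched-chain amino acid permease gene, at -1.69 ± 0.40. The peptidase genes varied, with pepN at 0.04 ± 0.19, pepC at -0.21 ± 0.20, pepDA at -0.72 ± 0.52 and pepO at -0.94 ± 0.35. The gene pepM was at -2.41 ± 0.94, but it lay in the dimmest 25% of probes with signals of 0.15 to 16.2 units, and its ratio was -0.29 with 50 units added to each signal. The list also contains bcaP, and its mean was -0.62 with bcaP and -0.89 without it. The list passed camera with the preset correlation (adjusted p = 9.05e-05) and did not pass with an estimated correlation (adjusted p = 0.602). Adjusted over the list alone 9 members passed, bcaP higher and the other 8, pepM among them, lower, against 0 over all probes.

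Of the purine list, 20 members were measured, 13 lower and 2 higher on both arrays, with a median of -0.67 (1.59-fold lower). Genes of the pathway to inosine monophosphate were lowest, with purC at -2.74 ± 0.53, purL at -2.61 ± 0.54, purH at -2.53 ± 0.22, purK at -1.84 ± 0.89 and purM at -1.55 ± 0.25. With 50 units added to each signal purC was at -1.55, purL at -2.01 and purH at -1.36, and 0 purine genes passed. The purF ratios had opposite signs on the arrays (mean 0.24 ± 0.50). Other members had ratios nearer 0, with guaB of the guanine branch at -0.79 and the salvage genes xpt at -0.55 and pbuX at -0.53. The regulator gene purR (0.49) and hpt (0.44) were the members higher on both arrays. The list passed camera with the preset correlation (adjusted p = 1.43e-04) and did not pass with an estimated correlation (adjusted p = 0.602). Adjusted over the list alone 7 members passed, all lower, against 0 over all probes.

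**Figure D2:**
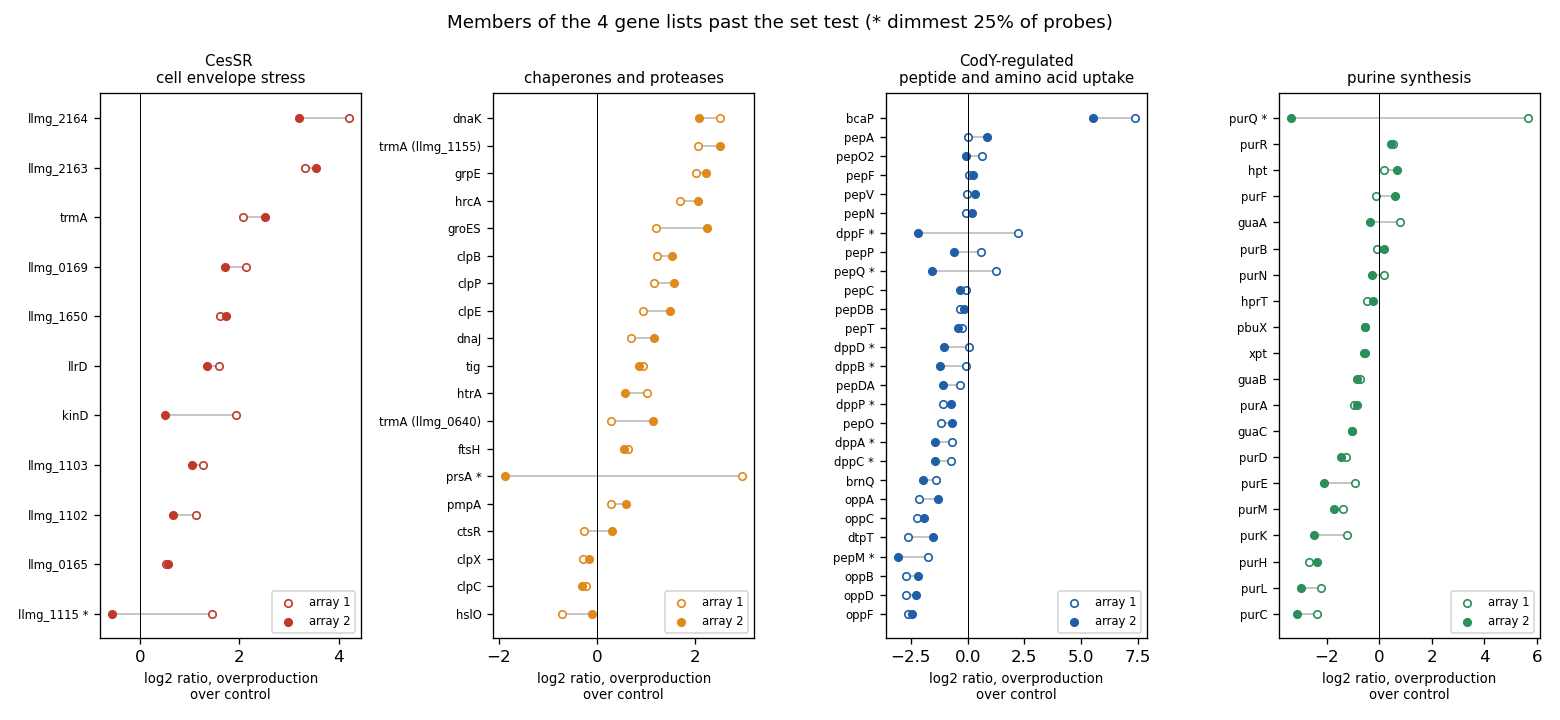
Log2 ratio of overproduction over control (horizontal axes) of each measured member of the 4 gene lists past the set test, with open circles for array 1, filled circles for array 2 and an asterisk for genes in the dimmest 25% of probes. Of the CesSR list 10 of 11 members lie above 0 on both arrays, and of the purine list 13 of 20 lie below 0 on both.

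The remaining lists did not pass camera, though some did under other settings: of 16 alternatives, 11 called the serine to cysteine list, 9 the pyrimidine list, 8 the ATP synthase list and 5 the sugar uptake list. Among amino acid genes, the arginine list (19 measured, adjusted p = 0.167) held members on both sides, 10 higher and 7 lower on both arrays. Adjusted over the list alone 8 passed. The synthesis genes argH (2.49 ± 1.01), argF (2.22 ± 0.21), argB (2.21 ± 0.75), argD (1.85 ± 1.06) and argE (1.36 ± 0.28) and the gene gltS (1.14 ± 0.06) were higher. Of the arginine deiminase pathway, which breaks arginine down, arcC1 (-1.39 ± 0.59) and arcD1 (-1.46 ± 0.30) were lower. With 50 units added to each signal argF was at 1.07, argB at 1.31 and argD at 1.02. Of the serine, threonine, lysine, methionine and cysteine list (24 measured, median -0.44, adjusted p = 0.0598), 15 members were lower and 4 higher on both arrays. Adjusted over the list alone 4 passed, metC (-2.44 ± 1.15) and cysK (-2.02 ± 0.95) lower and metF (2.03 ± 0.09) and dapA (1.71 ± 0.16) higher. The gene metF lay in the dimmest 25% of probes and was at 0.25 with 50 units added to each signal. Of the branched-chain amino acid synthesis list (11 measured, median -0.43, adjusted p = 0.167), 6 members were lower and 2 higher on both arrays. Its members included ilvD at -1.29 ± 0.62 in the dimmest 25% of probes, ilvB at -0.86 ± 0.21 and aldR at 1.83 ± 0.66, and with 50 units added to each signal these were at -0.45, -0.45 and 1.24. Of its members 6 lay in the dimmest 25% of probes, and for the 5 others the median was again -0.43, with 3 lower and 2 higher on both arrays. The mean of the list was -0.26 with all members and 0.11 over these 5, among which aldR had the highest ratio. The glutamate and glutamine list (17 measured, median -0.23, adjusted p = 0.123) had 6 members lower and 2 higher on both arrays, with the ammonium transporter gene amtB at -1.53 ± 0.53 (-0.93 with 50 units added). The histidine and aromatic list (26 measured, adjusted p = 0.759) had 7 members on each side, with tyrA at 0.86 and hisC at -0.46.

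Among genes of nucleotides, energy and translation, the pyrimidine list (15 measured, median -0.48, adjusted p = 0.0519) had 9 members lower and 1 higher on both arrays, with pyrE at -1.16 ± 0.38 and pyrR at -0.93 ± 0.16. The ATP synthase list (8 measured, median -0.62, adjusted p = 0.0598) had 6 lower and 1 higher, with atpA at -0.93 ± 0.35 and atpC at 0.71 ± 0.33. Sugar uptake genes (47 measured, median 0.27, adjusted p = 0.0676) were higher on both arrays in 23 cases and lower in 5, with ptcA at 1.26 ± 0.87. Glycolysis and fermentation genes (26 measured, median 0.26, adjusted p = 0.0956) were higher in 13 cases and lower in 5, with gapB at 1.30, pmg at 1.26 and ldh at 1.13. Ribosomal protein genes (47 measured, adjusted p = 0.103) had a median of -0.11 on array 1 and 0.56 on array 2, with rpmG at 1.66 ± 0.42. Aminoacyl-tRNA synthetase genes (24 measured, adjusted p = 0.865) were higher on both arrays in 9 cases and lower in 8, with pheS at -0.77 ± 0.02. In the oxidative stress and ribonucleotide reduction list (20 measured, median -0.09, adjusted p = 0.436), 7 members were higher and 8 lower on both arrays. Adjusted over the list alone 5 passed: the ribonucleotide reductase genes nrdH (-1.69), nrdE (-1.65), nrdI (-1.43) and nrdF (-1.42) were lower and the superoxide dismutase gene sodA (1.36) was higher.

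Among envelope and transport genes, the export list (12 measured, median 0.49, adjusted p = 0.103) had 7 members higher and 2 lower on both arrays, with ffh of the signal recognition particle at 1.92 ± 0.72 and the translocase gene secY at -1.23 ± 0.42. Cell wall genes (31 measured, adjusted p = 0.539) had a median of -0.05 against a mean of 0.11, the side on which the test put them, with mraY at 1.17 ± 0.04 and murB at -1.11 ± 0.69. Fatty acid and phospholipid genes (18 measured, median -0.18, adjusted p = 0.415) were lower in 9 cases and higher in 4, with the cyclopropane synthase gene cfa at -1.19 ± 0.05. Metal homeostasis genes (18 measured, adjusted p = 0.759) had a median of 0.06, on the side of the test, and a mean of -0.15. Their ratios included cadA at 1.46 ± 0.16 with a further probe at 0.65, and copB at -4.31 ± 5.05 in the dimmest 25% of probes, which was -0.36 with 50 units added to each signal. Of the multidrug and nisin list, 4 members were measured, 2 higher and 2 lower (adjusted p = 0.842). They were lmrP at -0.87, lmrA at 0.75, bcrA at -0.45 and lmrC at 0.10. No nis gene was among them, so the list says nothing on the nisin system genes. Cold shock and competence genes (18 measured, median 0.15, adjusted p = 0.204) were higher in 6 cases and lower in 3, with cspE at 2.17 ± 1.14. With an estimated correlation, a test left with 1 degree of freedom, 0 of the 22 lists passed.

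The ratios of the 2 arrays correlated across probes with a Pearson r of 0.256 (probes are not independent replicates). Among probes split into 4 equal groups by brightness, r from the dimmest to the brightest was -0.14, 0.58, 0.64 and 0.66. Outside the dimmest 25% of probes, 135 probes differed at least 2-fold on both arrays, 62 higher, 73 lower and 0 in opposite directions. In the dimmest 25% of probes 89 did so, 59 of them in opposite directions.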

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

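The offset, the intensity trend, the grid means, the lists without bcaP, the use of all probes and the held prior degrees of freedom were chosen after seeing the data. In limma, 0 probes passed over all probes, and the count was 272 without the dimmest 25% of probes, 65 with the duplicate correlation of spots, 45 with an offset of 50, 29 with that offset and spots at 0 kept, 5 with separate channels, 1 without moderation and 364 at an unadjusted p. It stayed at 0 with median centring, print-tip loess, scaling, the value table, grid means and the trend. All 45 probes of the offset were among the 272, and 36 were among the 65. The log2 ratio of bcaP passed without the dimmest 25% of probes (6.47), with the duplicate correlation (6.47), with separate channels (6.47), with the offset (5.79) and with the offset and spots at 0 kept (5.79). It ran from 5.54 to 7.39 when either array was left out, a value with no test since 1 array remains and one that always lies within the SD, and its adjusted p over the alternatives ran from 1.47e-66 to 0.681. The 4 lists stayed called in every set test run except with an estimated correlation and with fry, which called 0 and 0 lists. Those 2 tests rest on 1 residual degree of freedom, so hardly any list could pass them. The number called was 7 with median centring, print-tip loess, the value table, the duplicate correlation and separate channels, and 8 with scaling, either offset and ranks. Over the 16 alternatives the added lists were serine to cysteine synthesis (11), pyrimidines (9), ATP synthase (8), sugar uptake (5), glycolysis (2) and branched-chain synthesis (1). Among lists that did not pass, some turned side in the set test, with these means: branched-chain synthesis (0.11) and histidine and aromatic (-0.00142) without the dimmest 25% of probes, the latter also with the value table (-0.023), aminoacyl-tRNA synthetases with print-tip loess (-0.049) and all probes (0.00210), multidrug with the duplicate correlation and without moderation (-0.12 in both), and metals with print-tip loess (-0.13). Of the named genes other than bcaP, 50 of the 77 still tested passed without the dimmest 25% of probes, and 16 did with the prior degrees of freedom held at 4.17, where 26 probes passed in all. The gene lmrC turned sign with print-tip loess (-0.13). The cause of these was not tested. Not run, because the signals hold no background or spot marks, were no background correction, normexp with offset 0 and marked spots kept, and plain subtraction is what the signals already are. No further paired analysis was run, because the main fit is already paired: each array's ratio sets 1 overproducing against 1 control culture.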

Other observations

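The gene groups in this first paragraph were chosen after their values were seen, so their values describe the arrays and no set test was run on them. The riboflavin genes ribA (-2.49), ribB (-2.79) and ribD (-2.74) were lower on both arrays, as was the neighbouring llmg_1529 (-1.63). In the plp lipoprotein cluster, plpB (-2.74), plpC (-2.59), dar (-2.34) and plpD (-1.56) were lower on both arrays. The consecutive genes llmg_0501 (-2.45), llmg_0502 (-2.42), llmg_0503 (-1.81) and llmg_0504 (-1.41) were also lower on both. Of 8 arginine synthesis genes 8 were higher on both arrays, with a median of 1.61, and of 7 genes of the arginine deiminase cluster 5 were lower on both and 0 higher, with a median of -0.99. Genes numbered next to the CesSR pair were higher on both arrays, among them llmg_1644 (1.61), llmg_1645 (1.64) and the peptidyl-prolyl isomerase gene ppiB (1.30). The chaperonin gene groEL2 (1.43), absent from the fixed chaperone list under that name, was higher on both arrays, like groES (1.73). With 50 units added to each signal the dimmer of these genes had smaller ratios, such as plpC at -1.23, llmg_0501 at -1.85 and llmg_1529 at -1.03. None of these genes passed over all probes in limma (adjusted p from 0.112 to 0.981).

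Tests of the scatter of dim spots, dye bias, nisin and CodY were chosen after the result was seen. The tests on random removal, the prior degrees of freedom and neighbouring genes were set down before theirs. All of them came after the main results were known.

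Without the dimmest 25% of probes, limma called 272 probes against 0 with all probes. A smaller number of tests does not account for this, since in 100 removals of a random 25% of probes the highest count was 32 and the median 0. The scatter of dim spots is a candidate explanation: the robust SD of the half-difference between arrays was 2.19 times as large in the dimmest 25% of probes as in the rest. Most of the count depended on the single spread that the filtered fit assigned to every probe. With the prior degrees of freedom held at 4.17 the count for the same probes was 26. This is below the highest count of 32 from random removals, in which the prior was fitted anew. Those 26 probes, 8 higher and 18 lower, included bcaP, llmg_2163, llmg_2164, pacL, dnaK, grpE, argF, oppD, oppF, purC, purH, ribB and pbuO (adjusted p between 0.0338 and 0.0428).

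The CesSR and chaperone lists were higher, and the uptake and purine lists lower, in the overproducing cultures. Dye bias would turn the sign between the arrays with swapped dyes. Each of the 4 lists kept the sign of its median on both arrays, and the smallest of the 8 medians was 0.33 in size. The 4 lists had been picked by the mean of both arrays, in which an equal dye effect cancels. This outcome was therefore largely set by that choice and adds little on dye bias. Nisin acts on the cell envelope, and nisin given to the overproducing cultures alone may also raise the CesSR list (median 1.48). The labels do not say what the control cultures received, so this cannot be told apart from an effect of BcaP. The same holds for the chaperone, uptake and purine lists and for the other ratios here. An effect of any overproduced membrane protein was not tested either.

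A hypothesis for the lower oligopeptide transport genes is stronger repression by CodY, which binds branched-chain amino acids, after more of them enter through BcaP. It predicts that the branched-chain amino acid synthesis list is lower too. Its median was -0.43, with -0.74 on array 1 and -0.49 on array 2, but the list did not pass camera (adjusted p = 0.167). Of the alternatives, the centred value table alone called it, as lower. Among its 5 members outside the dimmest 25% of probes the median was again -0.43, while the mean was 0.11. The 2 higher of these were aldR (1.83) and aldB (0.78), and the 3 lower were ilvB (-0.86), ilvC (-0.76) and ilvE (-0.43). The uptake list, also of CodY targets, was mixed. Of its 19 members outside the dimmest 25% of probes, 12 were lower and 3, bcaP among them, higher on both arrays. Of its peptidase genes, pepN was at 0.04 and pepC at -0.21, while pepDA was at -0.72 and pepO at -0.94. These arrays therefore leave the hypothesis open.

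If the ratios reflect transcription units, genes with consecutive locus tag numbers may change together. Across the 1300 pairs of consecutive genes outside the dimmest 25% of probes and on different printing grids, the ratio of a gene on 1 array correlated with that of the next gene on the other array at r = 0.34. The highest r in 10000 shuffles of the gene order was 0.09 (permutation p = 1e-04, the smallest these shuffles can give), and r was 0.35 without the pairs that hold bcaP. Genes are not independent replicates. Neighbours thus shared part of their ratios across different arrays and different grids. Other features of the print layout, which was the same on both arrays, were not tested as a source.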
